A study of Mus musculus with 6 samples.

How the data were processed

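DNase-seq was deposited for 6 libraries of liver from mouse embryos at embryonic day 13.5 (strain C57BL/6NJ), numbered as biological replicates from separate tissue samples in the labels. There is a single group, and whether samples share a litter is not given. Per library the deposited files are 2 peak lists, a footprint list and a list of false discovery rates of the cut rate, all for assembly mm10 per the labels. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here, and peaks were called per library, with no pooling.

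The peak lists give each peak's position and a signal value by the authors; the score, p and q columns and the peak offset are constant and were not used. The signal values deposited by the authors are whole multiples of one step per library and were used only to describe, rank or filter peaks within a library. The deposited cut-rate lists give a false discovery rate, read as a q-value, per stretch of bases, from 0 to just under 0.05. The deposited footprint lists carry the constant 0.01 in their value column, whose meaning is not given in the sources used here, so footprints could not be ranked. The lowest listed rate within each peak stayed below 0.05 in the longer peak list of every library and below 0.001 in the shorter one. The longer list was the main list, as fixed before the data were examined, and the shorter list an alternative.

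Coordinates were compared with GRCm38.p6, the build that mm10 names: all peaks lay on chromosomes 1 to 19, X and Y and none ran past a chromosome end. Gene models were those of GENCODE for the same build, with 21938 protein-coding genes; hypersensitive site, enhancer and transfer RNA annotations came from RefSeq. Peaks of the 6 libraries were merged where they overlapped by 1 bp or more, and a site was counted in a library if one of its peaks overlapped it. A promoter site is a peak within 1 kb of any annotated TSS of a gene, and a distal site is one more than 1 kb from every TSS. Coordinates are 1-based.

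Before the data were examined 17 gene lists with 329 genes were fixed; Ahsp was not in the annotation. The named genes are a fixed set (among them Gata1, Hbb-bs, Alb, Kit, Spi1 and Gapdh), the 2 members of each list with most distal sites, up to 3 members of the neuronal, muscle and germ cell lists with a promoter site in all 6 libraries, and up to 3 members of the erythroid and hepatic lists with none in any library, by symbol; other genes named were chosen after their values were seen. Some genes that this rule names are not reported here. Promoter sites of list members were compared with those of all other protein-coding genes by Fisher's exact test (two-sided, across genes, which are not independent replicates), and distal sites by a two-sided permutation test against 10000 random lists of genes with a promoter site in all 6 libraries, both with Benjamini-Hochberg adjustment over the 17 lists. Motifs were 23 consensus patterns on both strands, searched in footprints widened by 5 bp on both sides, against control windows of the same width drawn in the same peaks outside every footprint, or within 75 bp of a site's midpoint. Libraries were compared by the exact two-sided sign-flip permutation test of the log2 ratio over 6 libraries, whose smallest p is 0.0312, and sites of erythroid and hepatic lists by Fisher's exact test, with adjustment over the motifs. Correlations across libraries have exact permutation p values over all pairings. P-values over libraries measure the spread between these 6 samples. For shared against single-library sites they cover only the spread of the single-library shares.

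The depth per library is known only through the signal step and covers 66.9 to 125 in units of 1e+06 reads if the signal is scaled to that number. Shares of sites in 1 library have 95% Wilson intervals. The tests were run on simulated data with known answers over 21938 genes drawn independently. The promoter test called the erythroid regulators, raised to 97% of genes, in 91.5% of 200 simulations. It called the neuronal list, lowered to 10%, in 98.5% and unchanged lists in 0.607%. The distal test called a list with a mean of 4 sites against 1.2 in 95.0% of 40 simulations, and no unchanged list. Observed means were smaller (2.40 for erythroid regulators and 1.75 for globin, heme and iron genes) and globin genes share sites. The simulated rates therefore need not carry over to these lists. A GATA log2 ratio of 2.61 made into 15000 windows was recovered as 2.60. Among motifs not planted there and found in 0.2% or more of control windows, the largest absolute log2 ratio was 0.370. Both sets of windows were drawn from the same random bases. The simulation therefore does not cover a difference in GC content between footprints and control windows.

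Alternatives fixed before the data were examined were the shorter peak list, promoter windows of 500 bp and 2 kb, a distal window of 100 kb, an equal number of strongest peaks per library, an overlap of 50%, presence in 4 or more libraries, lists matched on promoter CpG ratio (within 500 bp of the 5′ end, in 10 classes), all protein-coding genes as background, unwidened footprints, shifted control windows, whole sites, and leaving out each library in turn. The planned use of the stronger footprints by deposited score was not run. Alternatives added after seeing the data were the removal of sites within 1 kb of a transfer RNA gene, libraries 1 to 4 only, sites in 2 or more libraries, 1 gene of each cluster of neighbouring list members (5′ ends within 100 kb of each other) and distal sites only. Analyses used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.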

Results

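DNase I cuts chromatin most readily where nucleosomes are displaced, and DNase-seq maps those sites genome-wide. Liver of C57BL/6NJ mouse embryos at embryonic day 13.5 was profiled in 6 libraries, which the labels number as biological replicates 1 to 6 of a single group. The labels name no contrast, so the data bear on which regions were accessible in this tissue and on how well that repeated. At this stage the organ is the main site of blood formation as well as a developing gland, so gene lists of both lineages and of other cell types were compared. The deposited peak lists held 47248, 46820, 42517, 51671, 37281 and 40166 peaks in libraries 1 to 6, a mean of 44284 ± 5271 (SD, n = 6). The footprint lists held 146279, 108820, 113544, 89686, 91321 and 92371 footprints, a mean of 107004 ± 21673 (SD, n = 6). Within each library every peak signal value was a whole multiple of a fixed step, within 0.05 steps. If the signal is a read count scaled to 1e+06 reads, which the sources used here do not state, that step corresponds to depths of 125, 72.99, 87.2, 66.9, 77.1 and 69.8 in units of 1e+06 reads in libraries 1 to 6.

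The sites found in every library were mostly promoters. The peaks merged into 82809 sites, of which 19006 (23.0%) were present in all 6 libraries and 33304 (40.2%) in 1 library. Of the sites in all 6 libraries, 67.6% lay within 1 kb of an annotated transcription start site (TSS), 13.9% in introns, 14.96% between genes and 3.56% in exons. Among sites of 1 library the share near a TSS was 31.9%. Peaks at sites shared by all 6 had a median signal 4.95 ± 1.03 fold (SD, n = 6 libraries) that of peaks found in their own library alone. Over the 15 pairs of libraries the sites in both made up 51.3% ± 7.33 (SD) of the sites in either. Libraries 5 and 6 overlapped most, at 64.8%, and libraries 1 and 5 least, at 40.3%. Against 23.0% for sites shared by all 6 libraries, 35.4% were shared when only libraries 1 to 4 were merged, an alternative chosen after seeing the data.

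Promoters of most erythroid regulators and red cell membrane genes were accessible in all 6 libraries, and those of globin, heme and iron genes less uniformly. Of 15 erythroid regulators, 14 had a promoter site in all 6 libraries (93.3%, against 48.2% of other protein-coding genes; Fisher's exact test, adjusted p = 0.00121). They included Gata1, Klf1, Tal1 and Zfpm1, transcription regulators of the red cell lineage, and Epor, the erythropoietin receptor; Gfi1b had a site in 4 libraries. Of 19 genes of the red cell membrane and cytoskeleton, 18 had a site in all 6 (94.7%, Fisher's exact adjusted p = 0.000207), among them Slc4a1, the band 3 anion exchanger, and Sptb, the erythroid beta spectrin. The globin, heme and iron list reached 13 of 20 (65%, Fisher's exact adjusted p = 0.190), with the adult beta-globin genes Hbb-bs and Hbb-bt and the heme enzymes Alad, Urod and Fech in all 6. Alas2, the erythroid first enzyme of heme synthesis, had a promoter site in 3 libraries, Hbb-y in 2, and Hbb-bh1, Hba-x, Hba-a2 and Slc25a37 in none. All 22 housekeeping and cell cycle genes, Gapdh and Actb among them, had a site in all 6 (Fisher's exact adjusted p = 1.84e-06). Against 10000 random lists matched on promoter CpG ratio, the globin, heme and iron list was also above its matched genes (65% against 34.6%, permutation adjusted p = 0.00453), and with a 2 kb window it passed Fisher's exact test (adjusted p = 0.0332).

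Promoters of hepatocyte secreted protein and postnatal liver metabolism genes were accessible in all 6 libraries less often than those of other genes. Of 20 secreted plasma proteins made by hepatocytes, 1 had a promoter site in all 6 libraries (5%, against 48.3% of other genes; Fisher's exact test, adjusted p = 0.000268). That gene was Apoh. Alb, the albumin gene, and Ahsg and Ambp had no promoter site in any library, Apoa1 had one in 3, and Afp, alpha-fetoprotein, in 4. The Afp site of libraries 1 to 4 (90500872 to 90501020) lay inside the gene, near an internal annotated start site. The site at the 5′ end of Afp was found in library 2 only. The share of this list with a promoter site was 25%, 50%, 40%, 40%, 10% and 10% in libraries 1 to 6, a mean of 29.2% ± 16.9 (SD). Of 17 hepatoblast regulators, 5 had a site in all 6 (29.4%, Fisher's exact adjusted p = 0.167), with Cebpa and Foxa3 in all 6 and Hnf4a and Foxa2 in none. A start site of Sympk lies within 2 kb of one of Foxa3. Among 23 genes of postnatal liver metabolism 5 had a site in all 6 (21.7%, Fisher's exact adjusted p = 0.0180), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had none. Against lists matched on promoter CpG ratio the secreted protein list stood at 5% against 22.5% (permutation adjusted p = 0.0725), and the postnatal list at 21.7% against 23.7% (adjusted p = 1).

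Of 10 lists of other cell types, 8 were below other genes and those of stem and progenitor and of megakaryocyte genes did not pass. In all 6 libraries a promoter site was present for 3 of 24 macrophage and granulocyte genes (adjusted p = 0.00121) and 4 of 22 lymphoid genes (adjusted p = 0.00820) by Fisher's exact test. By that exact test 3 of 20 endothelial genes (adjusted p = 0.00607) and 4 of 22 stellate and mesenchymal genes (adjusted p = 0.00820) had one. By the same exact test the counts were 1 of 10 cholangiocyte genes (adjusted p = 0.0290), 4 of 20 neuronal genes (adjusted p = 0.0181), 3 of 21 skeletal and cardiac muscle genes (adjusted p = 0.00407) and 2 of 20 germ cell and pluripotency genes (adjusted p = 0.00130). The counts were 8 of 17 stem and progenitor genes (exact adjusted p = 1) and 4 of 16 megakaryocyte genes (exact adjusted p = 0.0966). By the exact test the megakaryocyte list passed with a 500 bp window (0.0296), with the shorter peak list (0.0171) and with equal numbers of strongest peaks (0.0290). Against CpG-matched lists its share was above that of the matched genes (25% against 21.3%, permutation adjusted p = 0.966). Kit and Runx1, which act in blood stem and progenitor cells, had sites in all 6 libraries and Cd34 in 5. Spi1, the gene of PU.1, had one in all 6, Csf1r and Pf4 in none, Pecam1 in 2 and Pdgfra in 6. Snap25, Map2 and Elavl4 were neuronal genes with a site in all 6, at 33.7, 24.4 and 33.8 on average as percentiles of their library's peak signal, against 93.1 for Gapdh. The muscle gene Ckm and the germ cell gene Gdf9, each with a site in all 6, have start sites of Klc3 and of Uqcrq within 2 kb, and those of Mylpf lie near Sept1 and Tbc1d10b; Ryr1 and Dazl have no such neighbour. Against CpG-matched lists the stellate (adjusted p = 0.00777), cholangiocyte (adjusted p = 0.0293), neuronal (adjusted p = 0.00272) and germ cell (adjusted p = 0.000850) lists stayed below by permutation, while the macrophage (0.373), lymphoid (0.321), endothelial (0.254) and muscle (0.319) adjusted p values did not pass. By Fisher's exact test the neuronal call was lost without library 5 (adjusted p = 0.0937), with a 2 kb window (0.0503) and when 4 libraries sufficed (0.533). In libraries 1 to 4 only, chosen after seeing the data, it was lost too (8 of 20, 40% against 53.0%, exact adjusted p = 0.305). The share of neuronal genes with a site was 65%, 60%, 45%, 60%, 30% and 40% in libraries 1 to 6. With 4 libraries sufficing the lymphoid (0.0519) and endothelial (0.0573) calls were lost too, and with the shorter peak list the cholangiocyte call (0.0572).

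**Figure D1:**
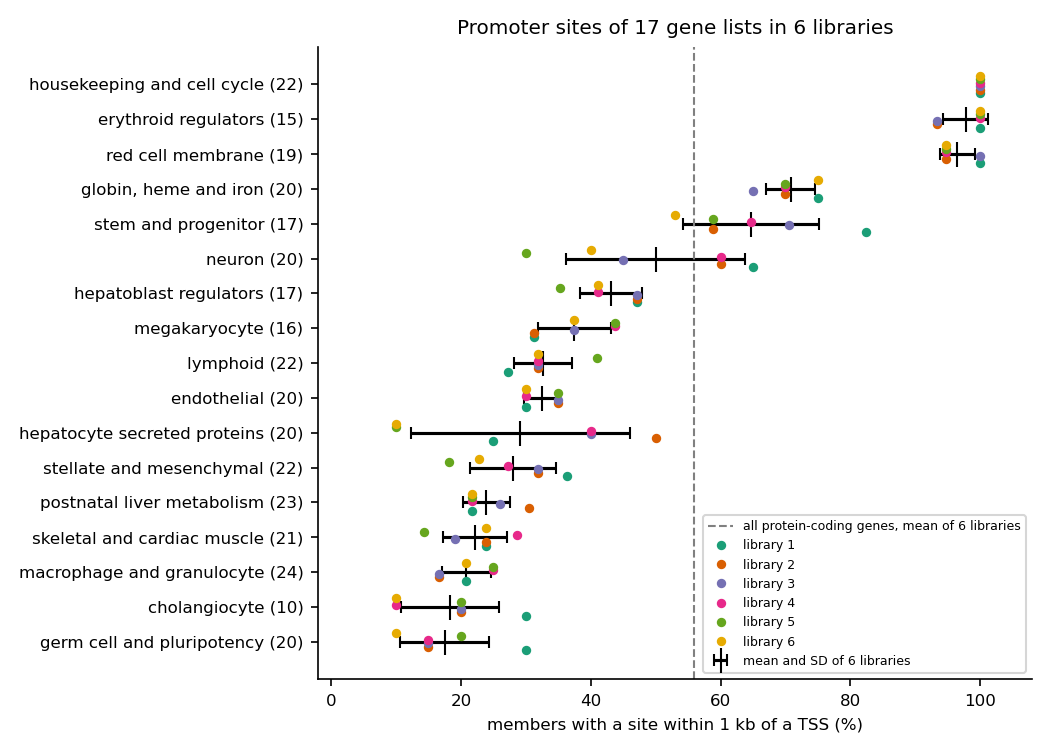
Percent of each list's members with a site within 1 kb of a TSS (horizontal axis), with 1 point per library, the mean and SD of the 6 libraries, the number of members in brackets and the mean of all protein-coding genes (55.9%) as a dashed line. The erythroid regulators (97.8% ± 3.44) and red cell membrane genes (96.5% ± 2.72) sit near the housekeeping genes, and the hepatocyte secreted proteins spread from 10% in libraries 5 and 6 to 50% in library 2.

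Distal sites were more numerous around erythroid regulators than around random genes. Erythroid regulators had a median of 2 distal sites present in all 6 libraries within 50 kb of their 5′ end, against a mean of 0.294 for the medians of random lists (permutation test with 10000 lists, adjusted p = 0.0187). The globin, heme and iron list also had a median of 2, against 0.270 (permutation adjusted p = 0.00340), but 7 of its 20 members are globin genes of 2 clusters that count the same sites. The 7 globin genes had a median of 3 and the 13 other members a median of 1. With 1 gene of each cluster, an alternative chosen after seeing the data, the list had a median of 1 and did not pass (permutation adjusted p = 1). This alternative cannot test the erythroid regulators, because none of their 15 members was removed. Their unadjusted permutation p stayed at 0.00220 and only its adjustment moved (0.0374). Zfpm1 and Cbfa2t3, a partner and a corepressor of red cell transcription factors, had 6 and 5 such sites, Slc4a1, Sptb and Tal1 had 3 each, and Gata1 and Klf1 had 2. The red cell membrane, macrophage and granulocyte, and housekeeping lists had a median of 1 and the hepatic lists 0, and none of the other 15 lists passed the test; the mean was 1.77 for the housekeeping list and 1.75 for the globin, heme and iron list. Trf, transferrin, had 2 distal sites, Foxa2 and Hnf4a had 1 each and Alb none. Among members of other lists without a promoter site in any library, Cyp1a2, Cd79a and Eng each had 4 distal sites nearby, Cd4, Tnnt2 and Tnp1 had 3, and Gp6, Pdgfrb and Stra8 had 2. Fcgr3 had 9, all of which lay within 1 kb of a transfer RNA gene. Both calls depended on the sites counted: within 100 kb the adjusted p was 0.0510 for the regulators and 0.454 for the globin, heme and iron list, and with the shorter peak list 0.196 and 0.0952 (permutation). In libraries 1 to 4 only, chosen after seeing the data, the permutation values were 0.190 and 0.0884, and without library 5 the regulators had 0.0635. The red cell membrane list passed within 100 kb (permutation adjusted p = 0.0442), without library 1 (0.0255) and without library 5 (0.0340).

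The beta-globin locus on chromosome 7 (GRCm38) held 12 sites, 5 of them in all 6 libraries. The promoters of Hbb-bt (site at 103813821 to 103814100) and Hbb-bs (103827801 to 103828120), the adult genes, were accessible in every library, and the site at the Hbb-y promoter (103853114 to 103853373) was called in libraries 5 and 6. Hbb-y is the embryonic epsilon-like gene. Upstream of it, intergenic sites in all 6 libraries lay at −6.08 kb (103859181 to 103859400), −7.89 kb (103861001 to 103861220) and −17.6 kb (103870741 to 103870980) from its start, at the positions that RefSeq annotates as hypersensitive sites HS1, HS2 and HS4 of the locus control region. The site at HS3 (103865765 to 103866080, at −12.7 kb) was found in 5 libraries, all but library 3, and that at HS6 (103877181 to 103877380, at −24.1 kb) in libraries 5 and 6. Each of these 5 sites held at least 1 GATA motif, and the HS2 and HS3 sites an NFE2 motif as well. Whole sites were searched here and at the loci below. By that search 48.8% of 6068 distal sites in all 6 libraries, away from the erythroid and hepatic lists, held a GATA motif. The deposited footprints numbered up to 6 per library in the HS2 site.

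The alpha-globin window on chromosome 11 held 22 sites, 4 of them in all 6 libraries. The site at −30.6 kb from the start of Hba-x (32245666 to 32245970, in an intron of Nprl3) overlaps the RefSeq enhancer R1, was present in all 6 libraries and held 3 GATA motifs. The sites at R2 (32250941 to 32251200, at −25.3 kb) and R3 (32256141 to 32256440, at −20.1 kb) were found in 4 and 5 libraries and that at R4 (32269021 to 32269280, at −7.25 kb) in 5. The Rm site (32265182 to 32265358) was found in libraries 5 and 6. Of the 22 sites 20 were called in library 1 and 5 in library 2, and 9 were found in 1 library. Hba-a1 and Hba-a2 are near-identical copies, so the absence of sites at Hba-a2 and the dense calls of library 1 around Hba-a1 are uncertain: how reads with several matches were treated is not given in the sources used here.

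**Figure D2:**
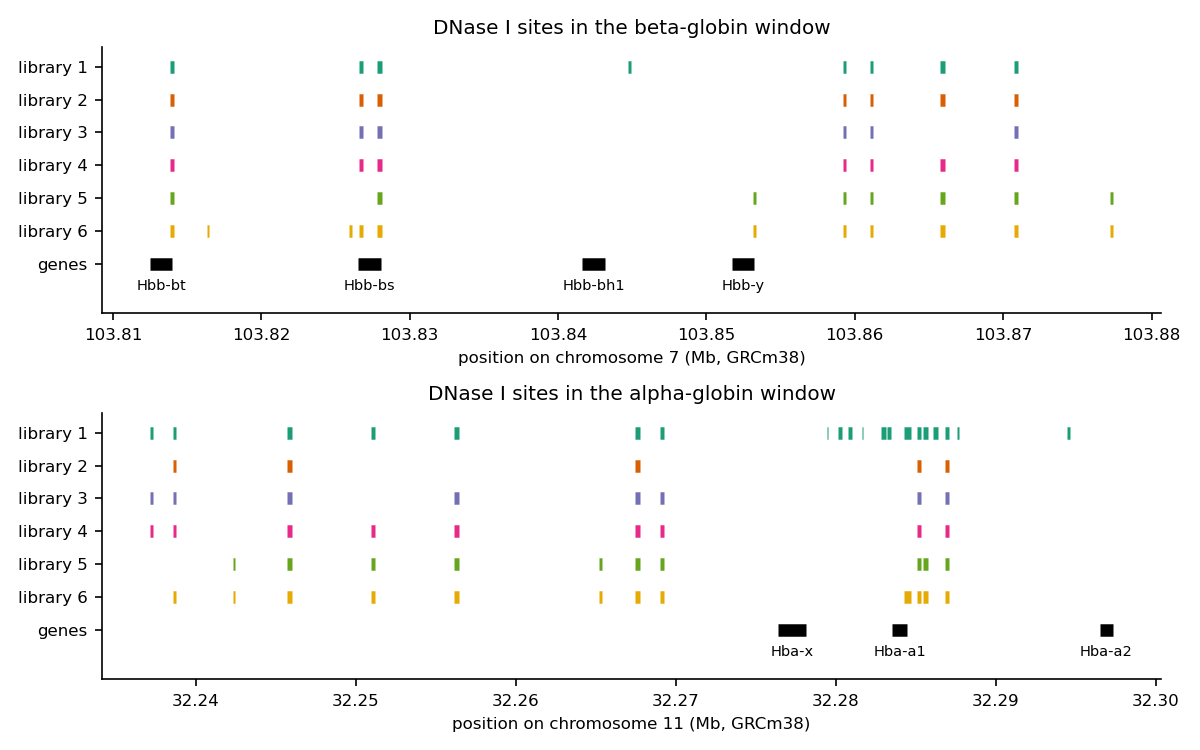
Positions (horizontal axis, Mb on GRCm38) of merged sites in the beta-globin window on chromosome 7 and the alpha-globin window on chromosome 11, a row for each library, with the globin genes as black bars. All 6 libraries share the sites at −6.08, −7.89 and −17.6 kb from the start of Hbb-y and at −30.6 kb from that of Hba-x, and library 1 alone has a dense run of sites around Hba-a1.

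Around Gata1 (chromosome X, 7959260 to 7978071), 4 of 12 sites within 20 kb of the gene were in all 6 libraries, among them an intronic site at 7971361 to 7971620 and an intergenic site at −15.5 kb from the annotated 5′ end (7993307 to 7993840), both with a GATA motif. The shared site at 7947801 to 7948220 lay outside Gata1, within 1 kb of a start site of another gene. The region of Klf1 (chromosome 8, 84901928 to 84905291) held 13 sites, 6 of them in all 6 libraries, including sites centred at −0.684 kb from its start (84901027 to 84901460) and at its start (84901781 to 84902220), each with 2 GATA motifs. The shared sites at 84893721 to 84894100, 84908461 to 84908880 and 84913141 to 84913420 lay outside Klf1, within 1 kb of start sites of other genes. From Alb (chromosome 5, 90460897 to 90476602) to Afp (90490737 to 90508907) 2 sites were found. A site within 1 kb of an Afp start site (90500872 to 90501020) was in libraries 1 to 4 and the site at the 5′ end of Afp (90490680 to 90490795) in library 2. At Hnf4a (chromosome 2, 163506808 to 163572910), 1 of 7 sites was in all 6 libraries, an intronic site 28.3 kb from the 5′ end (163534981 to 163535220) with none of the motifs searched.

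Footprints, short stretches protected from cutting, exceeded control windows most in NRF1, CTCF, SP/GC box, NFE2 and KLF motifs; the KLF consensus is shared by many KLF family proteins. Footprints outside the peaks, or with no free control window in the same peak after 50 draws, were left out. From 79.3% (library 1) to 92.1% (library 4) of the deposited footprints were tested. The CTCF motif was present in 2.37% ± 1.03 of tested footprints (SD, n = 6) and 0.0762% of control windows of the same width in the same peaks, a log2 ratio of 4.85 ± 1.03. The ratio was 2.87 ± 0.24 for the SP/GC box, 2.49 ± 0.70 for the NFE2 element and 2.32 ± 0.22 for the KLF motif, and NRF1 motifs were found in 245 to 314 footprints and 1 to 15 control windows per library. These motifs, YY1 (0.85 ± 0.52), the neuronal E-box (0.79 ± 0.20) and ETS (0.75 ± 0.26) were above control in 6 of 6 libraries (exact sign-flip permutation test, adjusted p = 0.0491). Below control in 6 of 6 were FOXA (−1.65 ± 0.16), the octamer (−0.93 ± 0.26), ONECUT (−0.65 ± 0.35), PU.1 (−0.51 ± 0.21), TEAD (−0.40 ± 0.17) and MEF2 (−0.35 ± 0.27), with the same adjusted p by that exact test. GATA was at 0.11 ± 0.53 (SD), above control in 3 of 6 libraries (exact adjusted p = 0.688). It was above control in libraries 4, 5 and 6 and below in libraries 1, 2 and 3. The shares were 5.29% against 3.30% in library 5 and 1.24% against 1.91% in library 1. The composite GATA and E-box motif was at 1.48 ± 1.05, above control in 5 of 6 (exact adjusted p = 0.0724). AP-1, CEBP, HNF4, NR5A2, RUNX and SRF did not pass either, and HNF1 was too rare to test. An unadjusted p of 0.0312 is the smallest this design gives, and no motif was called with unwidened footprints (smallest exact adjusted p 0.0521; 5 motifs above and 7 below at an unadjusted p under 0.05). There NRF1 could not be tested, and the ratio was 7.16 for CTCF, 3.34 for KLF and −3.23 for FOXA. YY1 (0.35 ± 1.297, exact unadjusted p = 0.531) and ETS (0.45 ± 0.42, exact unadjusted p = 0.125) were above control in 4 of 6 libraries. None was called with any 1 library left out (smallest possible exact p 0.0625) or in libraries 1 to 4 (0.125), where no unadjusted p was under 0.05. Footprints were richer in GC than control windows (62.3% to 65.6% against 57.5% to 59.8%). With control windows shifted by 100 bp the PU.1 ratio was 0.05 (exact adjusted p = 0.812), the octamer was not called (0.0820), and composite GATA and E-box, AP-1 and CEBP motifs were (0.0469).

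**Figure D3:**
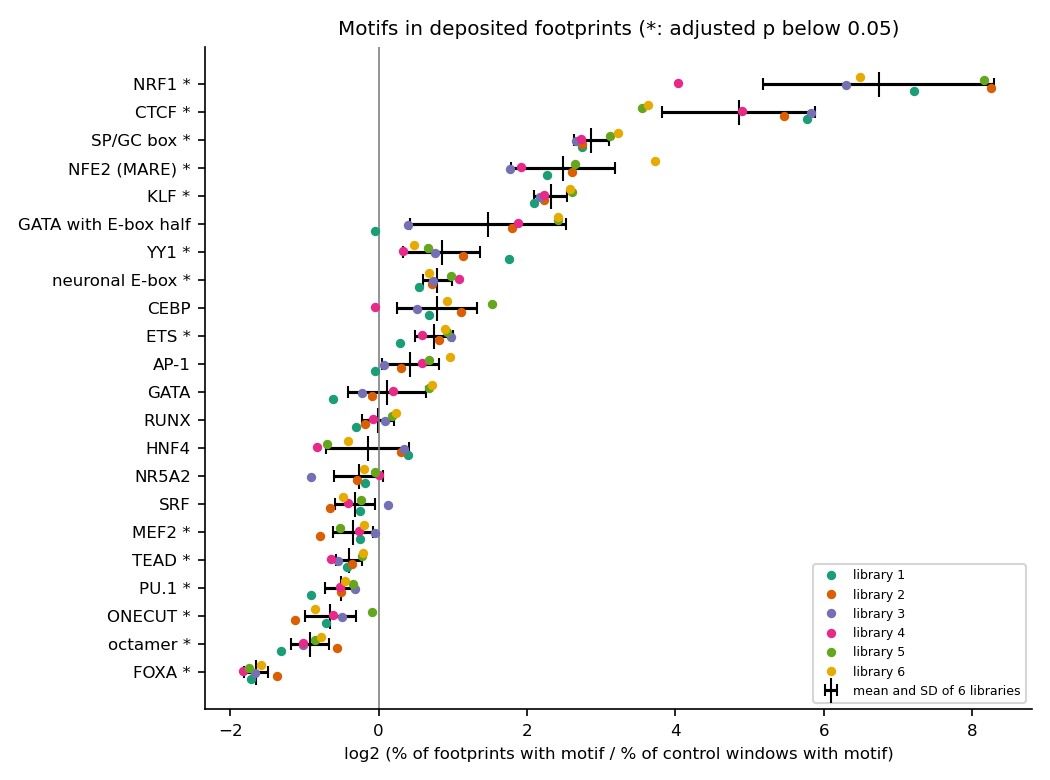
Log2 ratio of the percent of footprints with each motif to the percent of control windows with it (horizontal axis), 1 point per library with the mean and SD of 6 libraries; stars mark an adjusted p below 0.05. CTCF (4.85 ± 1.03), the SP/GC box (2.87 ± 0.24) and KLF (2.32 ± 0.22) lie above 0 in every library, FOXA (−1.65 ± 0.16) lies below 0 in every library, and GATA lies on both sides.

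GATA motifs at distal sites of red cell genes were compared with those of hepatic genes, which had few such sites. Of 82 distal sites present in all 6 libraries within 50 kb of the 3 erythroid lists, 46 (56.1%) held a GATA motif, against 0 of 10 around the 2 hepatic lists (Fisher's exact test across sites, adjusted p = 0.0260) and 32.3% of the 6068 other distal sites. No other of the 23 motifs passed. By the same exact test the call was lost under each alternative: 61 of 128 against 3 of 21 within 100 kb (adjusted p = 0.0940), and 60 of 82 against 3 of 10 when whole sites were searched (0.227). The counts were 30 of 46 against 0 of 6 in the shorter peak list (exact adjusted p = 0.0843), and 118 of 250 against 12 of 46 at sites in 2 or more libraries (0.111, chosen after seeing the data). The difference was 56.1 percentage points in the planned test, 33.4 within 100 kb, 43.2 with whole sites, 65.2 in the shorter peak list, which had fewer sites, and 21.1 at sites in 2 or more libraries.

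The 6 libraries differed in the sequence content of their distal sites. A GATA motif lay within 75 bp of the midpoint of 21.6%, 26.2%, 23.0%, 30.5%, 45.7% and 43.5% of the distal sites of libraries 1 to 6, a mean of 31.7% ± 10.4 (SD). The CTCF motif was present in 15.02%, 18.9%, 20.5%, 17.5%, 8.62% and 9.64%, a mean of 15.03% ± 4.92 (SD). For the CTCF share of distal sites, highest over lowest library, the ratio was 2.38, and 4.07 with the shorter peak list. Each library had 17898 to 26251 distal sites, and the 95% Wilson intervals, which cover counting error only, were 44.9% to 46.4% for GATA in library 5 and 25.6% to 26.8% in library 2. PU.1 motifs ranged from 1.24% in library 1 to 3.13% in library 5 and RUNX motifs from 6.28% to 10.01% in the same libraries. Of the promoter sites found in 2 or more libraries, libraries 1 to 6 recovered 81.8%, 85.4%, 84.0%, 85.9%, 69.3% and 73.9%. For distal sites with a GATA motif the values were 41.2%, 56.3%, 43.4%, 76.9%, 78.6% and 82.1%, and for those with a CTCF motif 72.0%, 91.1%, 84.6%, 94.2%, 35.6% and 43.3%. The reference sites include those of the scored library, so sites found in libraries 5 and 6 alone count as recovered by both. The motif shares of distal sites per library were chosen for description after seeing the data.

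**Figure D4:**
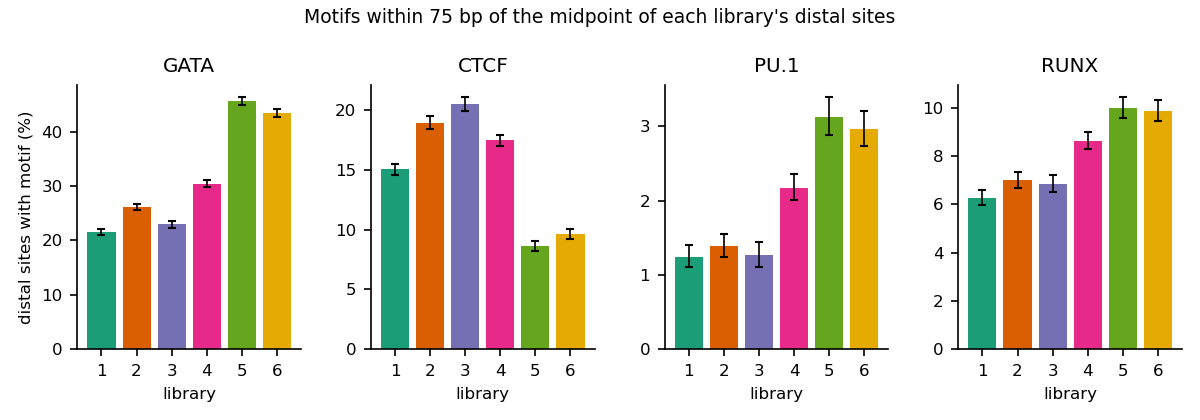
Percent of each library's distal sites (vertical axis, starting at 0) with a GATA, CTCF, PU.1 or RUNX motif within 75 bp of the midpoint, by library, with 95% Wilson intervals. GATA runs from 21.6% in library 1 to 45.7% in library 5, and CTCF from 8.62% in library 5 to 20.5% in library 3.

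Motifs at sites shared by all libraries were compared with those at sites found in 1 library. The share at shared sites is a single value that enters all 6 ratios. The SD and p of the ratios therefore reflect only the spread of the single-library shares. Shared sites more often held SP/GC boxes (16.4% against 2.54% ± 0.48, log2 ratio 2.71 ± 0.27), KLF motifs (26.6% against 10.3%, 1.38 ± 0.17), ETS motifs (3.53% against 0.386%, 3.25 ± 0.45) and NRF1 motifs (1.08% against 0.0528%, 4.50 ± 0.70) in each library. For GATA the ratio was −0.29 ± 0.73 (SD, n = 6). None of the 21 motifs tested passed: the smallest adjusted p was 0.0505 by the exact sign-flip permutation test, with 6 motifs above and 7 below at an unadjusted p under 0.05. With 6 libraries that test gives no unadjusted p under 0.0312, so passing after adjustment requires many motifs at that floor. The missing calls therefore do not show that the motif shares are equal. Among distal sites alone, a restriction chosen after seeing the data, the ratio was 0.52 ± 0.75 for GATA, 0.93 ± 0.49 for ETS and 1.48 ± 0.15 for the SP/GC box (SD, n = 6). There 6 motifs had an unadjusted p under 0.05, all more frequent at shared sites, with an adjusted p of 0.104 by the exact test.

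Peak number did not track footprint number over the 6 libraries (Pearson r = 0.265, exact permutation p = 0.633, adjusted p = 0.833; Spearman rho = 0.0857, exact p = 0.919, adjusted p = 0.919). Without libraries 4 and 5, the farthest from the median peak number, r was 0.744 over 4 libraries. In a family of 3 relations, 2 of them chosen after seeing the data, the depth recovered from the signal steps and footprint number gave r = 0.946 (exact p = 0.0208, adjusted p = 0.0625) and rho = 0.829 (exact p = 0.0583, adjusted p = 0.175). That relation rests on libraries 1 and 3, without which r was 0.243. Depth and peak number gave r = 0.121 (exact p = 0.833, adjusted p = 0.833) and rho = −0.143 (exact p = 0.803, adjusted p = 0.919), and r without libraries 1 and 3 was −0.730.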

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

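The tests of the GATA share were chosen only after the shares were seen, and that of depth also after the values it rests on were seen. Of 84 measures taken in all 6 libraries, 5 had a library far from the others by Dixon's ratio, where chance gives 4.2 at about 1 in 20.

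Library 1 stood apart in 3 of the 5 measures. Its signal step corresponds to a depth of 125 in units of 1e+06 reads if the signal is scaled to that number, against 66.9 to 87.2 in the other 5. Of its sites, 23.1% were found in no other library, against 9.49% to 14.3%. Its log2 ratio of PU.1 motifs in footprints was −0.91, against −0.52 to −0.33. Library 5 had a promoter site at 40.9% of the lymphoid genes, against 27.3% to 31.8%. Library 3 had a log2 ratio of NR5A2 motifs of −0.91, against −0.29 to 0.

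The share of distal sites with a GATA motif ran from 21.6% in library 1 to 45.7% in library 5, a 2.11-fold range. Among the 10000 strongest distal peaks of each library the range was 2.59-fold and among sites of 45% to 55% GC it was 1.91-fold, which argues against weak peaks and GC content as the whole source. Among libraries 2, 4, 5 and 6, of depth 66.9 to 77.1 in the same units, it was 1.74-fold (95% interval 1.70 to 1.79, counting error only). This argues against depth as the whole source, if the signal steps give depth. Libraries 1 and 3, left out there, had the largest depths by that reading and the lowest GATA shares (21.6% and 23.0%). A part played by depth stays open. The proportion of cell types in the dissected tissue stays open. The share of hepatocyte secreted protein promoters was 25%, 50%, 40%, 40%, 10% and 10% in libraries 1 to 6. The neuronal (30% and 40%) and stellate and mesenchymal (18.2% and 22.7%) lists were also lowest in libraries 5 and 6. The lymphoid list was highest in library 5 (40.9%). Of the sites in 2 or more libraries, libraries 5 and 6 recovered the most distal ones with a GATA motif (78.6% and 82.1%). They recovered the fewest with a CTCF motif (35.6% and 43.3%) and the fewest at promoters (69.3% and 73.9%). Library 4 recovered much of both motifs (76.9% for GATA and 94.2% for CTCF). These sites include those of the scored library, so recovery partly restates the motif shares. With a single group no biological explanation was tested, and dissection, litter and preparation stay open.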

How the results depend on the processing

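Tests with libraries 1 to 4 only, sites in 2 or more libraries, sites away from transfer RNA genes, 1 gene of each cluster, distal sites only and tests of the GATA and CTCF shares were chosen after seeing the data; the other alternatives were planned. The sites shared by all 6 libraries made up 23.0%, 30.2% with equal numbers of strongest peaks, 35.4% in libraries 1 to 4 and 24.7% to 27.5% with a library left out, where fewer libraries have to share a site. An overlap of 50% changes nothing by construction, since each peak lies wholly inside its merged site. Promoter lists below other genes numbered 10, 4 with random genes matched on promoter CpG ratio, and 9 to 10 with a library left out (9 without library 5); lists above numbered 3 throughout the latter. Over single lists and alternatives, 203 values kept their side of the threshold, 13 lost the call and 5 gained it. The 203 include uncalled values whose direction turned, such as the megakaryocyte list against lists matched on promoter CpG ratio.

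Lists with more distal sites numbered 2, but within a 100 kb window both lost the call and another list (red cell membrane) gained it, so 1 was called. With 1 gene of each cluster (neighbouring globin genes counted once) the globin, heme and iron list lost the call. The erythroid regulators kept theirs, but that alternative removes none of their members and so cannot test them. The count was 0 with the other peak list (permutation test; 4 at an unadjusted p under 0.05), 0 in libraries 1 to 4 only (4 at an unadjusted p under 0.05) and 2 to 3 with a library left out (without library 5 the red cell membrane list in place of the erythroid regulators). Motifs called in footprints numbered 8 above and 6 below control. By the exact sign-flip test they numbered 0 and 0 with footprints as deposited, not widened (5 and 7 at an unadjusted p under 0.05; NRF1 not testable), and 0 and 0 without replicate 1 or any other and in libraries 1 to 4 only (0 at an unadjusted p under 0.05), where 5 or 4 libraries cannot give an exact p under 0.0625 or 0.125. With control windows shifted by 100 bp PU.1 turned from −0.51 to 0.0466. GATA was the 1 motif called at erythroid against hepatic loci, with 0 motifs called by Fisher's exact test in a 100 kb window, with the whole site searched and with the other peak list (1 at an unadjusted p under 0.05 in each), and 0 at sites in 2 or more libraries (3 at an unadjusted p under 0.05). Except where fewer libraries set the smallest p or neighbouring genes were counted once, the cause was not tested. No motif was called between shared and single-library sites under any alternative (smallest adjusted p 0.0505 by the exact sign-flip test, 13 at an unadjusted p under 0.05 in the planned test). The smallest p that 6 libraries can give leaves little room to pass there. The relation of peak number against footprint number did not pass with the other list (r = 0.0969, exact permutation p = 0.851). The planned use of the stronger footprints was not run, because the deposited value is constant. Depth is known only through the signal step, so a site missing from a library may lie under its threshold rather than be closed: the libraries recovered 69.3% to 85.9% of the promoter sites found in 2 or more libraries.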

Other observations

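The tests of transfer RNA genes, of promoter CpG as an explanation and of libraries 1 to 4 alone were chosen only after the result was seen. Many transfer RNA genes overlapped sites: of 403 annotated by RefSeq, 206 (51.1%) overlapped a site in all 6 libraries, and 236 ± 15.1 (SD, n = 6) overlapped a peak per library. How reads with several matches were treated is not given, which matters for genes present in similar copies. Of the distal sites in all 6 libraries, 173 (2.81%) lay within 1 kb of one, against a median of 2 and at most 7 in 100 random placements of those genes. The placements were anywhere along the same chromosome and did not keep the clusters of these genes, so they are a rough expectation only. The protein-coding genes with most distal sites were Btn1a1 (15, of which 14 near a transfer RNA gene), Tmem107 (14 and 11) and Pom121l2 (12 and 12), named after their values were seen.

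Genes of the male-specific chromosome were accessible: Ddx3y, Uty and Eif2s3y on chromosome Y had a site in 6 of 6 libraries and Kdm5d in 5, all but library 6, and a site lay in the body of Xist on chromosome X in 6 of 6. The labels do not give the sex of the embryos. Of the strongest peaks, 5 were among the 10 strongest in all 6 libraries, including one over a ribosomal RNA gene on chromosome 17 (39846781 to 39846920, signal 95.1 to 207), one in Lars2 on chromosome 9 (123461881 to 123462160) and one in Zc3h7a on chromosome 16 (11144171 to 11144320), chosen after their values were seen. No regions were removed here for repeated sequence, and how reads with several matches were treated is not given. Whether these signals reflect accessibility is therefore uncertain.

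Some list genes had many distal sites, 9 for Fcgr3, and 100% of these lay within 1 kb of transfer RNA genes, which the annotation used for TSS does not hold. Around the members of the globin, heme and iron list 0% of the distal sites lay within 1 kb of a transfer RNA gene that the annotation used for TSS does not hold, so such genes do not account for the sites there. No biological explanation was tested.

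Few hepatocyte secreted protein genes had a promoter site in all 6 libraries (5% against 48.3% of other genes). In libraries 1 to 4 alone, 4 of 20 did (20%, Fisher's exact adjusted p = 0.00610), which argues against the libraries with fewest such promoters as the whole source. Against genes matched on promoter CpG ratio the difference was 5% against 22.5% (permutation adjusted p = 0.0725), so a general scarcity of sites at CpG-poor promoters may account for part of it; the call ended because the matched genes also have few sites, and a p that misses the threshold does not show equality. With a single group no biological explanation was tested.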
